A study of Homo sapiens with 2 samples.

How the data were processed

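Organoids derived from H9 human embryonic stem cells were sampled on days 30 and 62 of differentiation, dissociated with enzymes, and profiled by 10x Chromium 3' version 3 chemistry, per the labels' protocols. Sequencing was run on an Illumina NovaSeq 6000 with paired reads of 150 bases, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode, written by Cell Ranger 6.1.2 per the file headers and aligned to GRCh38 per the submitters' processing notes. The annotation release, the settings for calling cells, the strand setting and any later filter are not given in the sources used here. The values were checked to be whole numbers, and the files held 33538 genes, of which 6553 had 0 UMIs in both libraries. The analysis covered 2 libraries with 1 per day, so no statistical test between the days was possible, and no p-value or count of changed genes was made from cells.

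Cells were kept when they had at least 500 detected genes and at most 20% of UMIs from mitochondrial genes. This left out 562 of 10539 barcodes at day 30 (548 with few genes, 58 with high mitochondrial share) and 651 of 9530 at day 62 (202 and 520). The median mitochondrial share of kept cells was 1.58% and 3.58%, and the median share of ribosomal protein genes 12.6% and 7.91%. Scrublet, run per library through scanpy 1.11.5, called 0 doublets at day 30 and 1 at day 62. A caller that marks so few of these cells has not worked, so no doublets were removed, and unmarked doublets may remain in every class.

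Both libraries were clustered together without integration, because library and day were the same thing. Counts were scaled to 10000 per cell and log transformed, and 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, fixed seed) gave clusters 0 to 20. Clusters were called by a class name followed by "like" from fixed marker genes. How the markers were scored was set after the data had been seen. The score was the mean of the 8 highest marker levels of a class, each relative to the highest cluster. It ran over markers detected in at least 10% of the cells of any cluster. A name needed 5 markers detected in at least 10% of the cluster's own cells and a score of at least 0.5. Where another class held more markers among the 10 leading genes, that class gave the name if it scored at least 0.5. Leading genes were ranked by fold over the mean of the other clusters with 5 CPM added, among genes detected in at least 25% of cells. Clusters whose median UMIs lay under 1/3 of their own library's, with no marker of their own among the leading genes, stayed unnamed. Unnamed clusters were 1, 2, 3, 10, 11, 12 and 13. A class was compared between days only where each day had at least 100 of its cells, which held for neuron-like cells alone. No comparison within progenitor-like cells was made, because 1 library held nearly all of them.

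UMIs were summed over all kept cells, or over neuron-like cells, and divided by the total to give CPM. Ratios of day 62 to day 30 are log2 of the ratio of CPM with 1 CPM added, and a gene is counted as at least 2-fold higher or lower on that scale. Intervals on CPM are exact Poisson intervals, intervals on a ratio are exact conditional binomial intervals without the added 1 CPM, and intervals on shares are exact (Clopper-Pearson) binomial intervals, all at 95%. They cover counting error and not the spread between organoids or libraries. Genes needed at least 20 UMIs over both libraries to count as measured. Of 43 fixed gene lists, those with at least 4 measured members were summarised by the median of their log2 ratios and its percentile among 10000 random lists of the same size, drawn from genes of similar mean expression. Shares of cells with a UMI were compared after each cell was thinned at random to 2000 UMIs. This left out 1683 of the kept cells at day 30 and 1183 at day 62, and thinning to 500 UMIs, used for 1 test of inhibitory genes, left out 0.

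The genes named in the text were chosen by a rule. For the whole library it took the 12 largest and 12 smallest ratios among genes with at least 20 CPM in a library, leaving out mitochondrial, ribosomal protein and clone-named genes, and for neuron-like cells the 8 largest and 8 smallest. From each list it took up to 4 members with the highest mean CPM and up to 2 more with the largest absolute ratio, and it always allowed a fixed set of transmitter, dorsal identity and regional genes and the HOX genes of groups 1 to 8. AQP4, CSF1R, EMX1, FOXA2, GDF15, GFAP, HLA-B, HSPA1B, NEUROD1, POU2F2, POU5F1, SIX6, STC1, TTR, TYROBP and ZIC1 fall outside the rule and were chosen after their values were seen. Some genes that the rule allows are not reported here. The cell filter, the clustering settings, the markers, the gene lists, the rule for named genes and the summaries were fixed before the data were examined. Gene positions come from GENCODE release 29 on GRCh38, in which 33456 of the 33538 gene identifiers were found, 33071 with the same symbol.

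The ratio, percentile and thinning steps were tested on simulated data. In the simulated whole library of 19271 genes, the 95% interval held the true ratio for 96% of 50 genes changed 2-fold up, 96% changed 4-fold up, 94% changed to 0.5 and 98% changed to 0.25 of their level, and for 95.6% of unchanged genes. In simulated neuron-like cells of 17217 genes these shares were 100%, 94%, 100% and 96%, and 95.6%. Of unchanged lists of 15 genes, 2.5% in the whole library and 3% in neuron-like cells fell outside percentiles 2.5 to 97.5, and 100% of lists changed 2-fold lay above 97.5 in both. Apart from the changed genes, both simulated libraries came from the same profile with counting noise alone, and list members were drawn at random. The simulation therefore does not cover lists of genes that vary together or libraries that differ in many genes. For a simulated gene with an expected share of 14.8%, thinning gave 14.9% in shallow and 14.7% in deep cells, against 18.9% and 55.7% before thinning.

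Alternatives were other scalings (TMM factors from edgeR 4.0.16, totals without mitochondrial and ribosomal genes, each cell weighted alike), added values of 0.5 and 5 CPM, minimums of 0 and 100 UMIs per gene, all barcodes, a stricter cell filter (at least 1500 genes, at most 10% mitochondrial UMIs; 7388 and 6739 cells), Leiden resolutions 0.5 and 2, each library clustered alone, clustering without cell cycle, mitochondrial and ribosomal genes, and thinning to 1000 or 4000 UMIs. Those chosen after seeing the data left out cells with doublet scores above the limit of the top 5% (457 and 415 cells whose removal stands in for a doublet call; 71 and 36 cells tied at the limit stayed), used named clusters alone, left out cluster 0, or added the shallow clusters 2 and 11 to the neuron-like cells. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, matplotlib 3.10.9 and R 4.3.3.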

Results

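Gene expression was measured in single cells dissociated from organoids that were differentiated from H9, an established human embryonic stem cell line, toward the medullary spinal trigeminal nucleus. This hindbrain nucleus relays pain, temperature and touch from the face. Organoids were taken on day 30, named the early stage in the labels, and on day 62, named the late stage. Each day was represented by 1 library made with 10x Chromium 3' chemistry, and the values are counts of unique molecular identifiers (UMIs) per gene and cell. The day 30 library held 58819700 UMIs in 10539 cell barcodes and the day 62 library held 65451487 UMIs in 9530 barcodes. After filtering, 9977 cells with a median of 5490 UMIs and 2361 detected genes remained at day 30, and 8879 cells with a median of 6242 UMIs and 2834 genes at day 62. The kept cells gave 58409565 and 64481033 UMIs, so that 3 UMIs correspond to 0.0514 and 0.0465 counts per 1e+06 UMIs (CPM). Day and library were the same thing in this design. No difference between the days was therefore tested against replicates, and every comparison describes these 2 libraries, with 95% intervals that cover counting error only.

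Neuron-like cells were the largest named class in both libraries. Cells named progenitor-like were seen mainly at day 30 and cells named astrocyte-like at day 62, though progenitor markers also scored high in the latter. Neuron-like cells made up 56.8% of the kept cells at day 30 (5663 cells; exact binomial interval 55.8 to 57.7%) and 46.2% at day 62 (4104 cells; 45.2 to 47.3%). Progenitor-like cells, which contained SOX2 and VIM transcripts of neural stem cells, made up 11.3% at day 30 (1130 cells; 10.7 to 11.96%), and 2 cells at day 62 joined their cluster. Cells with transcripts of neuronal precursors made up 4.77% at day 30 (476 cells; 4.36 to 5.21%) and 3 cells at day 62 joined them. These shares hung on the clustering, at 13.7% and 3.92% with Leiden resolution 0.5. There a cluster with 1366 cells of day 30 took this name, and at day 62 the counterpart of the neuron-like cluster 16 did. Astrocyte-like cells made up 14.3% at day 62 (1274 cells; 13.6 to 15.1%) and 0 of 9977 cells at day 30 joined their clusters, as was also so for the neuron-like clusters 16, 18 and 20. The day 62 share was 9.39% at Leiden resolution 2 and 9.54% with each library clustered alone. These cells held 346 CPM of SPARCL1, 319 CPM of BCAN and 894 CPM of SOX2, while AQP4 was at 0 UMIs and GFAP, an intermediate filament of mature astrocytes, was at 0.666 CPM. The remaining 27.1% of day 30 cells and 39.4% of day 62 cells lay in clusters that were left unnamed by a scoring rule set after the data had been seen.

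The 2 libraries shared few clusters, so the classes were held by different clusters on the 2 days. Neuron-like cells lay in clusters 0, 5, 6, 8 and 9 at day 30 and in clusters 14, 15, 16, 18 and 20 at day 62, progenitor-like cells lay in cluster 4, and astrocyte-like cells lay in clusters 17 and 19. Cluster 17 scored higher for progenitor markers (0.992) than for astrocyte markers (0.830) and took its name from its leading genes. Cluster 19 scored 0.791 for both. The names of these clusters therefore do not show that progenitor-like cells were absent at day 62. Cluster 19 held 430 of the astrocyte-like cells and was shallow, with a median of 3879.5 UMIs. The nuclear transcript MALAT1 made up 0.452% of its UMIs against 8.69% in the other day 62 cells. Its mitochondrial share was 7.43% against 3.57%, and its ribosomal protein share 18.0% against 9.09%. Whether its barcodes held whole cells was not tested. Hypoxia and glycolysis genes such as STC1, HK2 and VEGFA led cluster 0 beside SST. A cluster found in 1 library may reflect that library and not a cell type. The order of the neuron-like shares is not interpreted, since leaving cell cycle, mitochondrial and ribosomal genes out of the clustering gave 55.4% at day 30 and 64.3% at day 62, as 1568 of the 1615 day 62 cells of the unnamed cluster 12 then lay in neuron-like clusters.

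**Figure D1:**
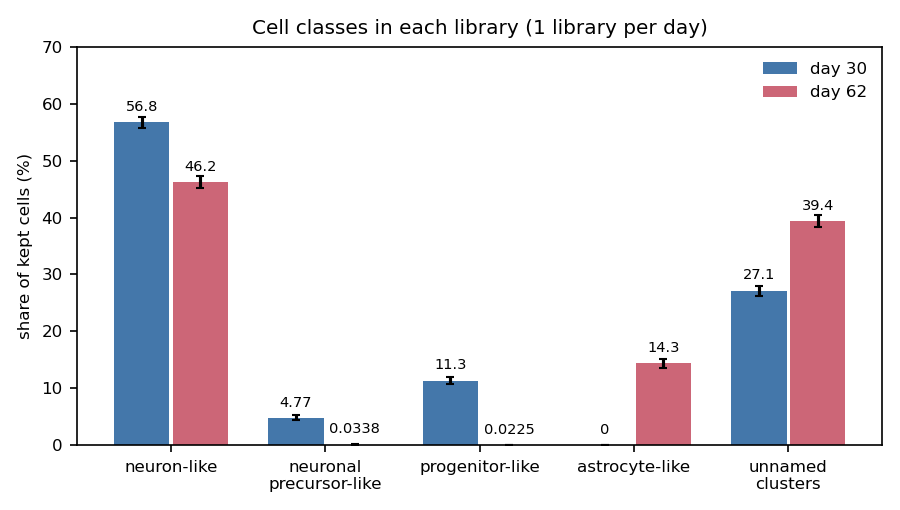
Share of kept cells (%, y axis) in each cell class (x axis) for the day 30 library (blue) and the day 62 library (red). Bars are shares within 1 library and error bars are exact binomial 95% intervals for counting error; astrocyte-like cells were at 14.3% at day 62 and 0 at day 30, and progenitor-like cells at 11.3% at day 30.

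The first comparison asked how expression in the whole organoid differed between the early and the late stage. The genes with the largest ratios included genes of glia and of stress responses, and those with the smallest ratios included genes of inhibitory interneurons and newborn neurons. Among the 7685 genes with at least 20 CPM in a library that entered the rule for named genes, the 12 largest ratios included SPARCL1 and BCAN, which encode matrix proteins of astrocytes, at 76.1 against 0.257 CPM and 74.1 against 1.93 CPM. CRYAB, a small heat shock protein, was at 445 CPM at day 62 and 8.37 CPM at day 30, a ratio of 53.2 (counting interval 48.6 to 58.3). The transcription factor genes NEUROD6 and NEUROD2 were 62.5 and 32.9 times higher at day 62 (44.6 to 90.5 and 27.0 to 40.6). ONECUT1, an early-born neuron transcription factor gene, was at 28.4 CPM at day 30 and 3.30 CPM at day 62 (log2 ratio −2.77).

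The 12 genes with the largest ratios fell into 3 sets by the cells that held them. SPARCL1, BCAN, PTGDS and PMP2 were highest in the astrocyte-like clusters, where PTGDS, a prostaglandin synthase, reached 1233 CPM and PMP2, a lipid-binding protein, 432 CPM. GPNMB, CRYAB, LGALS3, MT2A and S100A11 were highest in cluster 13, an unnamed day 62 cluster of 748 cells, where CRYAB reached 2727 CPM and the galectin gene LGALS3 194 CPM. GPNMB, a glycoprotein of lysosomes, rested on 9 UMIs at day 30 and 4934 at day 62 (log2 ratio 6.07). NQO1, a quinone reductase, was at 169 CPM in cluster 19 and 134 CPM in cluster 13. NEUROD2 and NEUROD6 were highest in the neuron-like cluster 15, which they helped to define, at 222 and 130.1 CPM. The 12 genes with the smallest ratios were held mainly by neuron-like cells of day 30. They included PAX8 and LHX1, transcription factor genes of inhibitory interneurons in the hindbrain and spinal cord, and the noncoding transcripts LHX1-DT (−2.09) and LHX5-AS1 (−2.70), with PAX8 at 114 against 19.5 CPM (−2.49) and LHX1 at 95.7 against 21.6 CPM (−2.10). NKX6-1 and MECOM, both transcription factor genes, had log2 ratios of −2.47 and −2.22, the axonal adhesion gene CNTN2 −2.22, the synaptic organizer C1QL1 −2.82, CPXM1 −2.12 and NHLH1, a factor of newborn neurons, −1.99. HBD, a globin gene, was at 57.4 CPM at day 30 and 2.497 CPM at day 62. Reads of HBD could be shared with near-identical globin genes, and the strand setting of the counting, which bears on LHX5-AS1, is not given in the sources used here. On GRCh38, SPARCL1 (ENSG00000152583) lies on chromosome 4 at 87473335 to 87531061, CRYAB (ENSG00000109846) on chromosome 11 at 111908565 to 111923722, and ONECUT1 (ENSG00000169856) on chromosome 15 at 52756989 to 52791078.

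**Figure D2:**
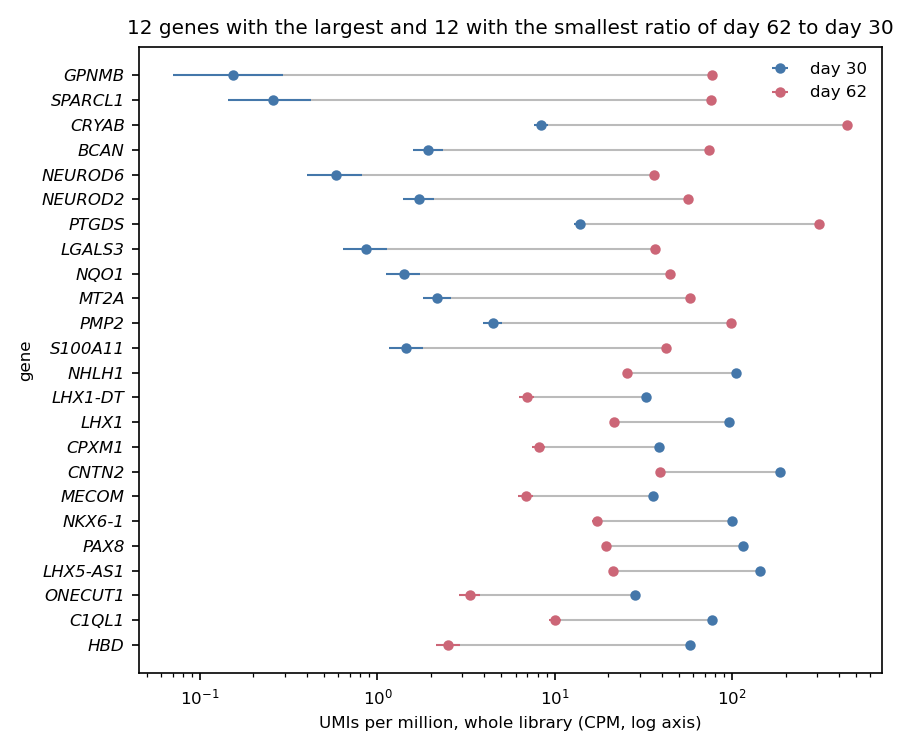
Expression (CPM, log axis) of the 12 genes with the largest and the 12 with the smallest ratio of day 62 to day 30 among the genes that entered the rule, in all kept cells of each library (blue, day 30; red, day 62). Points are values of 1 library, horizontal bars are exact Poisson 95% intervals for counting error, and grey lines join the 2 values; GPNMB and SPARCL1 lie farthest apart at 0.154 against 76.5 and 0.257 against 76.1 CPM.

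The medians of 5 lists of neuronal signalling genes lay above those of at least 97.3% of random lists, though many members differed by less than 2-fold, and the median of immature neuron genes lay below nearly all of them. Of 24 transmitter receptor genes, 13 were at least 2-fold higher, 0 were 2-fold lower and 11 lay between, with a median log2 ratio of 1.04 (above 100% of 10000 random lists matched on expression, whose median was 0.34). The GABA receptor subunit gene GABRA2 was at 41.0 against 2.89 CPM, and GABRB2 had a log2 ratio of 2.26. Of 25 voltage-gated channel genes, 9 were at least 2-fold higher and 0 lower (median 0.79, percentile 99.9), among them the sodium channel genes SCN1A (27.4 against 2.96 CPM) and SCN2A (74.3 against 26.6 CPM) and the calcium channel gene CACNA1E (log2 ratio 2.30). Of 27 synaptic genes, 6 were at least 2-fold higher and 0 lower (median 0.45, percentile 97.4), with the active zone gene PCLO at 246 against 78.3 CPM and the kinase gene CAMK2B at 46.7 against 14.8 CPM. Of 6 genes for glutamate transport and synthesis, 2 were at least 2-fold higher and 0 lower (median 0.88, percentile 99.6), led by SLC17A6, the vesicular glutamate transporter of subcortical neurons, at 69.0 against 25.5 CPM. Among 17 neuropeptide genes, 8 were at least 2-fold higher and 2 lower (median 0.97, percentile 100). TAC1, which encodes substance P, was at 148 against 21.3 CPM, NTS (neurotensin) at 53.3 against 3.30 CPM and SST (somatostatin) at 222 against 309 CPM, and the nociceptin gene PNOC had a log2 ratio of −1.11. The 12 inhibitory neuron genes had a median of −1.31, below every random list, with 7 at least 2-fold lower and 1, PTF1A, higher at 2.44 against 0.274 CPM. PAX2 was at 72.6 against 212 CPM, the GABA synthesis gene GAD2 at 32.1 against 119.7 CPM and the glycine transporter gene SLC6A5 at 23.99 against 88.8 CPM. The 18 immature neuron genes had a median of −0.68 (percentile 0.02), with 3 at least 2-fold lower, and DCX was at 749 against 1118 CPM and SOX11 at 484 against 1151 CPM.

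Progenitor and cell cycle genes differed by member, and most astrocyte genes and most immediate early and heat shock genes were at least 2-fold higher at day 62. Of 23 cell cycle genes, 7 were at least 2-fold lower and 0 higher (median −0.36, percentile 0), among them MKI67 at 4.13 against 15.2 CPM, UBE2C at 5.21 against 21.6 CPM and BIRC5 with a log2 ratio of −1.80, while the replication clamp gene PCNA was at 57.3 against 35.1 CPM. Of 15 neurogenic factor genes, 9 were at least 2-fold lower and 3 higher (median −1.20, percentile 0). HES6 was at 210.1 against 583 CPM and DLL3 at 48.7 against 113 CPM, and the 3 higher genes were NEUROD1, NEUROD2 and NEUROD6. Of 13 NOTCH pathway genes, 3 were at least 2-fold lower and 2 higher (median −0.63, percentile 0), with HES5 at 153 against 267 CPM and HES1 at 22.0 against 5.75 CPM. Of 18 radial glia genes, 8 were at least 2-fold higher and 0 lower (median 0.52, percentile 98.9), with HOPX at 58.3 against 4.69 CPM and SOX2 at 285 against 201 CPM. Of 17 astrocyte genes, 10 were at least 2-fold higher and 0 lower (median 1.64, percentile 100), including CLU at 416 against 139 CPM and S100B at 23.5 against 1.25 CPM. Of 12 immediate early and heat shock genes, 7 were at least 2-fold higher and 0 lower (median 1.14, percentile 100), with FOS at 615 against 271 CPM and DNAJB1 at 361 against 93.2 CPM. HSPA1A was at 635 against 291 CPM and shares reads with its near-identical copy HSPA1B. Of 10 p53 target and apoptosis genes, 4 were at least 2-fold higher and 0 lower (median 0.91, percentile 99.98), and GADD45A was at 212 against 84.2 CPM. Of 11 endoplasmic reticulum stress genes, 4 were higher and 1 lower by at least 2-fold (median 0.41, percentile 97.0), with DDIT3 at 496 against 136 CPM and DDIT4 at 217 against 540 CPM. Of 16 glycolysis and hypoxia genes, 4 were at least 2-fold lower and 0 higher (median −0.66, percentile 0), with VEGFA at 68.6 against 169 CPM and GAPDH at 1036 against 1726 CPM.

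These whole-library values mix the make-up of each library with levels inside its cells. The median log2 ratio over 19270 genes was 0.29 with scaling to total UMIs and 0.02 with trimmed mean (TMM) scaling. The TMM factors were 0.873 at day 30 and 1.146 at day 62. Positive values below the log2 ratio of these factors have no scaling-free direction. TMM scaling gave list medians of 0.076 for synaptic genes, 0.44 for voltage-gated channels and −1.07 for immature neuron genes.

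**Figure D3:**
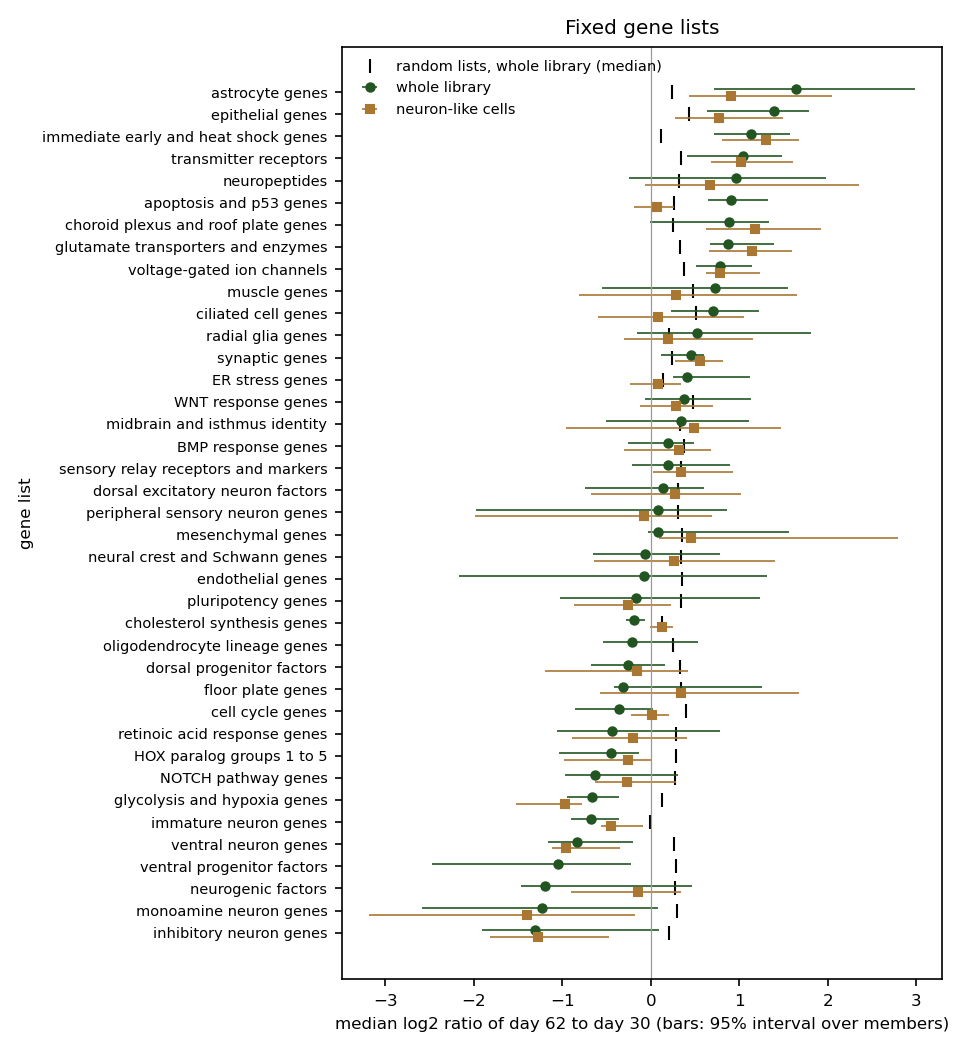
Median log2 ratio of day 62 to day 30 (x axis) of each fixed gene list (y axis) in the whole library (green circles) and in neuron-like cells (brown squares), with bars for the 95% interval over resampled members. Black ticks mark the median of random lists matched on expression in the whole library; astrocyte genes lie highest at 1.64 and inhibitory neuron genes lowest at −1.31 in the whole library.

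The next comparison was made within neuron-like cells alone, to leave out the other classes. Nearly all of these cells lay in different clusters on the 2 days. The ratios therefore still mix the kinds of neuron present with levels inside each kind. The genes with the largest ratios included 4 transcription factor genes, NFIA, NFIB, NEUROD2 and NEUROD6, and those with the smallest included PRPH and ONECUT1. NFIB was at 283 CPM at day 62 and 3.26 CPM at day 30, a ratio of 87.0 (72.5 to 105), and NFIA at 61.1 against 1.32 CPM. NEUROD2 and NEUROD6 were at 111 against 2.18 CPM and 73.4 against 0.828 CPM. PRPH, which encodes the intermediate filament peripherin, was at 20.7 against 175 CPM, and ONECUT1 was at 5.03 against 41.3 CPM (log2 ratio −2.81).

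The other genes with the largest ratios among 7530 in neuron-like cells were IGFBP5, which encodes a growth factor binding protein (75.9 against 1.90 CPM), CYP26B1, a retinoic acid degrading enzyme (45.9 against 0.856 CPM), GRIN3A, a glutamate receptor subunit (48.0 against 1.05 CPM), and NTS (105.9 against 3.86 CPM). NEUROD2, NEUROD6 and GRIN3A also led cluster 15, and NFIB led cluster 16, where it reached 905 CPM. In progenitor-like cells of day 30, NFIB and NFIA were already at 96.5 and 115 CPM. The other genes with the smallest ratios were HBD (−3.65), the transcription factor genes EBF2 (−2.92) and IRX1 (−2.87), C1QL1 (−2.88), TRIL (−2.83) and the glucose transporter gene SLC2A1 (12.4 against 76.6 CPM). SLC2A1 was at 244 CPM in cluster 0, the day 30 cluster led by hypoxia genes. On GRCh38, NFIB (ENSG00000147862) lies on chromosome 9 at 14081843 to 14398983 and NEUROD2 (ENSG00000171532) on chromosome 17 at 39603536 to 39609777.

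Within neuron-like cells the medians of the signalling lists also lay above those of nearly all random lists. Transmitter receptor genes had a median of 1.02 (12 of 24 at least 2-fold higher, 0 lower, percentile 100), with GABRA2 at 77.4 against 3.78 CPM and GRIN2B at 121 against 35.3 CPM. Voltage-gated channel genes had a median of 0.78 (11 of 25 higher, 0 lower, percentile 100), with SCN1A at 32.5 against 1.85 CPM, and synaptic genes one of 0.56 (5 of 27 higher, 0 lower, percentile 99.97), with SV2B at 10.2 against 0.524 CPM. Glutamate genes had a median of 1.15 (3 of 5 higher, 0 lower, percentile 99.9) and neuropeptide genes one of 0.67 (8 of 17 higher, 1 lower, percentile 99.9), with TAC1 at 238 against 30.8 CPM and CARTPT at 66.1 against 5.74 CPM. The interval over members of the neuropeptide genes held 0 here too (−0.0635 to 2.36). Inhibitory neuron genes had a median of −1.27 (6 of 11 lower, 0 higher, percentile 0), with PAX2 at 128 against 311 CPM and GAD2 at 57.9 against 175 CPM. The 18 immature neuron genes had a median of −0.44 (2 lower, 1 higher, percentile 0.24), with NHLH1 at 45.5 against 112 CPM and MAPT, which encodes tau, at 470.4 against 233 CPM. Glycolysis and hypoxia genes had a median of −0.97 (8 of 16 lower, 0 higher, percentile 0), but one of −0.08 without cluster 0, a setting chosen after the data were seen. Immediate early and heat shock genes had a median of 1.31 (7 of 12 higher, 0 lower, percentile 100), with FOS at 705 against 234 CPM. Astrocyte genes had a median of 0.91 (6 of 14 higher, percentile 100), a list that holds NFIA and NFIB, and CRYAB was at 27.5 against 0.607 CPM. At day 62, 14.3% of kept cells were astrocyte-like, against 0 at day 30, and no doublets were removed. Whether RNA of other cells lay in neuron-like barcodes was not tested. These values alone therefore do not show expression of astrocyte genes or CRYAB in neurons. Medians in neuron-like cells were 0.07 for p53 genes (percentile 33.8), 0.09 for endoplasmic reticulum stress genes (44.4; 0.52 without cluster 0), 0.02 for cell cycle genes (2.75) and −0.14 for neurogenic factors (2.55). The median over 17253 genes was 0.20 with totals, and a pseudocount of 5 CPM gave 0.68 for transmitter receptor genes.

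The regional identity of the organoids was read from HOX genes, which mark position along the hindbrain and spinal cord, and from genes of neighbouring regions. HOX genes of paralog groups 2 to 4 were abundant in both libraries, and most were lower at day 62. HOXB2 was at 231 CPM at day 30 (227 to 235) and 98.9 CPM at day 62 (96.4 to 101), a log2 ratio of −1.22. HOXB3 was at 159.5 and 146 CPM, HOXA3 at 143 and 106.5 CPM, HOXB4 at 131 and 69.2 CPM and HOXC4 at 92.2 and 40.4 CPM. HOXB5 was at 8.44 CPM at day 30 and 0.682 CPM at day 62, and HOXA5 at 8.41 and 9.12 CPM. Of 14 measured HOX genes of groups 1 to 5, 4 were at least 2-fold lower and 0 higher (median −0.45, percentile 0), and the median was −0.25 within neuron-like cells (percentile 0.07), where HOXB2 was at 282 and 139 CPM and HOXB3 at 206 and 255 CPM. Genes of groups 6 to 8 lay at 0.890 CPM or below in both libraries, the highest being HOXB7 at day 30. Of the forebrain genes, EMX1 and SIX6 had 0 UMIs in both libraries, LHX2 was at 9.83 and 11.9 CPM and DLX2 at 1.99 and 1.36 CPM, and OTX2 was at 0.394 and 0.233 CPM and EN1 at 0.788 and 0 CPM. Dorsal and intermediate progenitor genes were present, with PAX3 at 95.3 and 74.4 CPM and IRX3 at 69.8 and 58.1 CPM, and 3 of 15 measured dorsal progenitor factors were at least 2-fold lower and 1 higher (median −0.26, percentile 0). ZIC1 was at 0.0171 and 0.124 CPM and the floor plate genes SHH at 0.959 and 0.682 CPM and FOXA2 at 0.171 and 0 CPM. On GRCh38, HOXB2 (ENSG00000173917) lies on chromosome 17 at 48540894 to 48544989 and HOXB5 (ENSG00000120075) at 48591257 to 48593961.

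**Figure D4:**
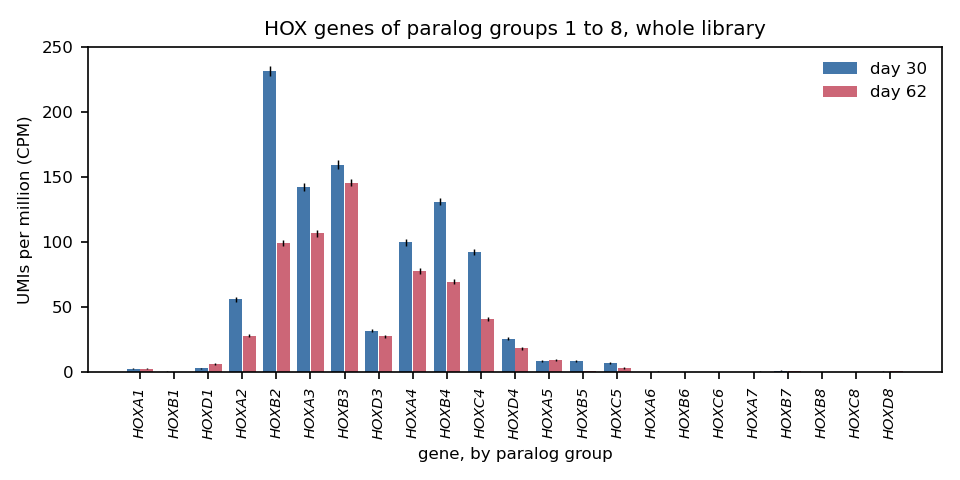
Expression (CPM, y axis) of the HOX genes of paralog groups 1 to 8 (x axis, ordered by group) in all kept cells of the day 30 library (blue) and the day 62 library (red). Bars are values of 1 library and error bars are exact Poisson 95% intervals for counting error; genes of groups 2 to 4 carry most of the signal, led by HOXB2 at 231 and 98.9 CPM, and genes of groups 6 to 8 lie at 0.890 CPM or below.

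The last comparison asked which transmitter and which dorsal neuron identity the neuron-like cells carried. Because depth per cell differed, each cell was thinned to 2000 UMIs, which left out 262 of the neuron-like cells at day 30 and 112 at day 62. Cells with a UMI of an inhibitory gene (GAD1, GAD2, SLC32A1 or SLC6A5) made up 47.1% of 5401 neuron-like cells at day 30 (45.8 to 48.4%) and 21.1% of 3992 at day 62 (19.9 to 22.4%), and 63.6% and 34.8% before thinning. Cells with a UMI of SLC17A6 made up 4.96% at day 30 (4.40 to 5.58%) and 13.3% at day 62 (12.3 to 14.4%), and 10.2% and 25.7% before thinning. Neither kind of gene was seen in 48.1% and 65.9% of the thinned neuron-like cells, and both were seen in 0.185% and 0.326%. As background, 0.555% of progenitor-like cells at day 30 and 1.36% of astrocyte-like cells at day 62 held a UMI of SLC17A6, and 5.37% and 2.21% a UMI of an inhibitory gene. The median depth before thinning was 6147 and 6770 UMIs in these neuron-like cells, 6377 in the progenitor-like cells and 9971 in the astrocyte-like cells.

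Transcription factor genes of dorsal hindbrain neuron types were found in more neuron-like cells than background cells. LBX1, a factor of dorsal association neurons, was seen in 38.7% of thinned neuron-like cells at day 30 and 23.4% at day 62 (3.61% of progenitor-like and 1.53% of astrocyte-like cells), PAX2, which marks dorsal inhibitory neurons, in 34.3% and 14.3% (3.52% and 2.04%), and LHX1 in 18.6% and 4.26% (1.48% and 0.510%). TLX3, a selector of excitatory sensory relay neurons, was seen in 9.17% and 10.6%, shares whose intervals overlap (8.41 to 9.97% and 9.63 to 11.6%), against 0.925% and 0.510% in the background classes. The related relay factors LMX1B and PHOX2A were seen in 3.41% and 2.43% (background 0.185% and 0.255%) and in 4.89% and 2.63% (0.740% and 0.340%), POU4F1 in 2.22% and 2.73% (0.0925% and 0.340%), and DRGX in 1.43% and 0.752% (0.0925% and 0.0850%). SLC17A6 was seen in 28.3% of TLX3-positive neuron-like cells at day 30, against 2.61% of TLX3-negative ones, and in 41.9% against 9.94% at day 62. Inhibitory genes were seen in 5.86% of TLX3-positive cells and 51.3% of TLX3-negative ones at day 30, and in 4.03% and 23.2% at day 62, while 71.1% of PAX2-positive cells held an inhibitory gene at day 30 and 58.6% at day 62. The peptide gene TAC1 was seen in 3.93% of neuron-like cells at day 30 and 21.2% at day 62 (0.463% of progenitor-like and 3.74% of astrocyte-like cells), the calcium-binding protein gene CALB2 in 0.667% and 6.59% (0.185% and 0.595%), and SST in 21.6% and 13.3% (3.89% and 3.57%). NTS was seen in 4.28% at day 62 (astrocyte-like 1.36%), and its 0.592% at day 30 lay below the 0.740% of progenitor-like cells. Before thinning these shares were 8.25% and 36.6% for TAC1, 1.77% and 13.6% for CALB2 and 15.0% and 21.8% for TLX3. All transmitter genes and factors of this comparison except PHOX2A, and the peptide genes TAC1 and SST, were markers used to name neuron-like clusters. Their excess over the background classes may therefore be partly built in. The share of SLC17A6 at day 30 was 6.53% without cluster 0.

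**Figure D5:**
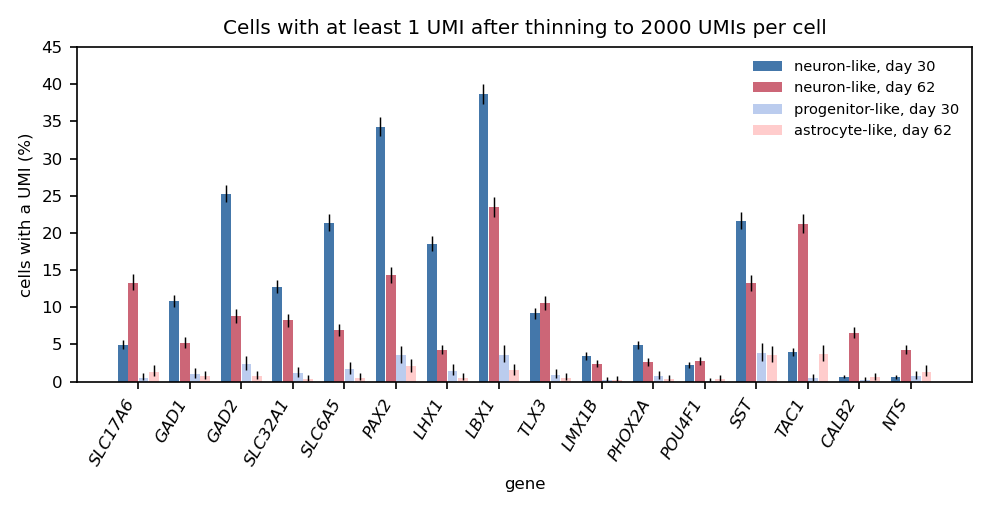
Share of cells with at least 1 UMI (%, y axis) of transmitter, identity and peptide genes (x axis) after thinning each cell to 2000 UMIs, in neuron-like cells (dark bars; blue, day 30; red, day 62) and in the background classes (pale bars; progenitor-like, day 30; astrocyte-like, day 62). Error bars are exact binomial 95% intervals for counting error; SLC17A6 was at 4.96% and 13.3% and GAD2 at 25.3% and 8.79% of neuron-like cells.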

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

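Named clusters alone, neuron-like cells without cluster 0, neuron-like cells with the shallow clusters 2 and 11, and the removal of cells with the highest doublet scores were chosen after seeing the data. No list median that lay apart from 0 by the interval over its members changed sign. Under alternatives 740 list medians stayed within that interval and 40 moved beyond it. Leiden resolution 0.5 changed the sign of 8 of 35 lists in neuron-like cells and TMM scaling of 10 of 75 lists. The reported medians of these lists were at most 0.29 in size, the largest being that of WNT response genes in neuron-like cells. Among them were dorsal excitatory, sensory relay and BMP response genes in the whole library, and p53, stress and cell cycle genes in neuron-like cells. TMM scaling gave 0.67 for glutamate genes, 0.076 for synaptic genes, 0.44 for voltage-gated channels and −1.07 for immature neuron genes in the whole library, and 0.53 for voltage-gated channels in neuron-like cells. Its construction shows the cause, a shift of all genes. With 5 CPM added, glutamate genes were at 0.61 and voltage-gated channels at 0.42 in the whole library, and transmitter receptors at 0.68 and voltage-gated channels at 0.61 in neuron-like cells. Weighting each cell alike gave 0.67 for synaptic genes. Of the single gene ratios, 509 stayed within their counting interval, 552 moved beyond it and 1 with a 2-fold difference reversed. Signs changed for 8 of 46 of these ratios at Leiden resolution 0.5, 7 of 46 with each library clustered alone, 3 of 46 at resolution 2 and 3 of 100 with TMM. The reversed ratio was SOX2 in neuron-like cells, at 1.28 and at −0.33 with Leiden resolution 0.5, and the cause was not tested. The neuron-like share at day 30 was 65.9% and 50.3% at resolutions 0.5 and 2, 44.4% with each library clustered alone, 55.4% without cell cycle, mitochondrial and ribosomal genes, 44.1% of all barcodes, 69.98% of strictly filtered cells, 77.9% of cells in named clusters and 72.5% with the shallow clusters. At day 62 the same settings gave 41.3%, 40.9%, 43.3%, 64.3%, 39.6%, 56.1%, 76.2% and 56.9%, so the order of the days depends on the clustering. Without the cycle, mitochondrial and ribosomal genes, 1568 of 1615 day 62 cells of the unnamed cluster 12 lay in neuron-like clusters, as their cluster scored 0.526 for neuron markers and cluster 12 0.460, on either side of the 0.5 a name needed. Without them the share at day 62 was 46.6%. Neuronal precursor-like shares were at 13.7% and 3.92% with resolution 0.5 and at 17.3% and 4.24% of all barcodes. Progenitor-like cells at day 30 were at 10.5% with each library alone, 12.05% without the cycle genes, 9.98% of all barcodes, 13.5% of strictly filtered cells and 15.5% of named clusters, and astrocyte-like cells at day 62 at 9.39% at resolution 2, 9.54% alone and 23.7% of named clusters. Thinning to 1000 and 4000 UMIs and no thinning gave SLC17A6 shares of 3.16%, 8.51% and 10.2% at day 30 and 8.83%, 21.0% and 25.7% at day 62, and inhibitory shares of 31.2%, 58.9% and 63.6% and of 13.9%, 29.5% and 34.8%. At day 30 resolution 0.5 gave 4.32% for SLC17A6 and 50.9% for inhibitory genes, resolution 2 gave 51.6% for inhibitory genes, and leaving out cluster 0 gave 6.53% for SLC17A6. It also took the glycolysis and hypoxia genes of neuron-like cells from −0.97 to −0.08 and the endoplasmic reticulum stress genes from 0.09 to 0.52. The order of the days in both shares was the same under each of these settings. Of the class shares under alternatives, 49 moved beyond their interval and 43 did not, and of the thinned shares 102 did and 90 did not. Keeping the 1 called doublet changed 0 results, a setting that tests nothing here. No paired analysis was possible because each day has 1 library, and for the same reason no library could be left out and no other split of the samples exists.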

Other observations

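The progenitor-like cluster of day 30 and an astrocyte-like cluster of day 62 were both rich in SOX2 (1012 and 989 CPM) and VIM (8371 and 8043 CPM). Cluster 4 held 1130 cells with a median of 6194 UMIs and cluster 17 held 844 cells with a median of 12411 UMIs. This comparison of clusters was chosen after the data were seen, left out the 20 genes that lead either cluster, and had a median log2 ratio of 0.19 over 14790 genes. Cell cycle genes were lower in cluster 17, with a median of −1.005 (12 of 23 at least 2-fold lower, 0 higher, percentile 0), MKI67 at 21.8 against 89.1 CPM and UBE2C at 18.8 against 120.3 CPM. Of 13 astrocyte genes, 10 were at least 2-fold higher in cluster 17 and 0 lower (median 1.47, percentile 100), which is not interpreted, because markers among them gave cluster 17 its name. NOTCH pathway genes had a median of −0.50 (4 of 11 lower, 2 higher, percentile 0.04), with NOTCH1 at 71.7 against 181 CPM and HES1 at 68.4 against 18.5 CPM. The 12 cholesterol synthesis genes had a median of −0.56 (percentile 0.01), with HMGCS1 at 419 against 739.9 CPM, and HOX genes of groups 1 to 5 one of −0.66 (percentile 0), with HOXB2 at 68.8 against 145 CPM. Inhibitory neuron genes had a median of −1.73 (7 of 11 lower, 2 higher, percentile 0) and immature neuron genes one of −0.77 (percentile 0). Other neuronal lists went the other way, with voltage-gated channels at 0.88 (9 of 20 higher, 0 lower, percentile 99.8), transmitter receptors at 0.79 (7 of 19 higher, 0 lower, percentile 98.9) and neuropeptides at 0.87 (7 of 14 higher, 2 lower, percentile 98.7). Endoplasmic reticulum stress genes were at 0.79 (percentile 99.9) and immediate early and heat shock genes at 0.78 (percentile 99.95). Transcripts of neurons, in both directions, and of stress responses thus also differed between these clusters.

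Several fixed lists described other cell types and pathways. Of 5 measured monoamine genes, 3 were at least 2-fold lower at day 62 and 2 lay between (median −1.22, percentile 0), with TH, the rate-limiting enzyme of catecholamine synthesis, at 28.2 against 79.0 CPM, and 11 ventral neuron genes had a median of −0.84 (3 lower, 0 higher, percentile 0), with GATA3 at 0.0931 against 5.55 CPM. Retinoic acid response genes had a median of −0.44 (3 of 11 lower, 2 higher, percentile 0.04), with CRABP1 at 754 against 1570.2 CPM and CYP26B1 at 27.2 against 0.907 CPM. Cholesterol synthesis genes had a median of −0.19 in the whole library, and BMP response genes one of 0.20 (1 of 10 higher, 0 lower, percentile 16.2), below the median of random lists, with a negative sign under TMM scaling. Immune genes other than AIF1 stayed low: AIF1 was at 361 CPM in cluster 19, where TYROBP, PTPRC and CSF1R had 0 UMIs. CALCA, the gene for calcitonin and its related peptide, was at 17.4 against 0.205 CPM, and was highest in the unnamed clusters 13 (81.8 CPM) and 12 (34.6 CPM) and at 1.66 CPM in neuron-like cells of day 62. The mesenchymal genes DCN and LUM were at 3.71 and 3.91 CPM at day 62, the choroid plexus gene TTR at 0.0775 CPM, the oligodendrocyte gene MBP at 15.9 CPM, and the pluripotency genes POU5F1 and NANOG at 0.155 CPM each. The choroid plexus and roof plate list had a median of 0.89 (4 of 9 higher, 0 lower, percentile 100), and 1.17 in neuron-like cells, and epithelial genes one of 1.39 (4 of 7 higher, 0 lower, percentile 100), with KRT8 and KRT18 at 18.7 and 15.3 CPM at day 62.

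In the 3 patterns that follow, the tests for forebrain-like neurons, for depth, for unnamed clusters and for nuclei were chosen after the result was seen. In neuron-like cells, thinned shares with a UMI of NFIB were 0.518% and 27.5% at days 30 and 62, of NEUROD2 or NEUROD6 0.370% and 24.3%, of ONECUT1 6.76% and 0.476%, and of POU2F2 37.7% and 14.8%. In progenitor-like cells of day 30 and astrocyte-like cells of day 62 these shares were 17.5% and 33.1% for NFIB, 0.0925% and 1.36% for NEUROD2 or NEUROD6, 0.370% and 0 for ONECUT1, and 3.89% and 1.78% for POU2F2. The NFIB share alone therefore does not show expression in neurons, but NFIB was at 905 CPM in the neuron-like cluster 16 and 463 CPM in cluster 15, above the 268 CPM of the astrocyte-like cluster 17. NEUROD2 and NEUROD6 also mark forebrain neurons, but 1611 cells with a UMI of either held 1.64 times the HOX level of the other 2493 (1236 against 753 CPM), which argues against forebrain-like cells. The forebrain list summed to 13.9 CPM in them and 30.3 CPM in the others, and to 2.41 CPM in them without LHX2. The NEUROD2 or NEUROD6 share was 24.8% among PAX2-positive cells of day 62, 18.3 times the larger of the day 30 and astrocyte-like shares. For TLX3-positive cells that ratio was 4.01 with 23 cells. Their share was 5.45% (3.49 to 8.07%), against 0.606% at day 30 (0.125 to 1.76%) and 1.36% in astrocyte-like cells (0.779 to 2.20%). The test could not decide, because it required the lower end of the interval to reach 3 times the larger of these. PAX2-positive cells thus also held these genes, at a share near the 24.3% of all neuron-like cells of day 62. Whether a separate group of neurons arose beside unchanged PAX2-positive ones cannot be decided, since a new group with PAX2 would give the same value. At day 62 the share was 34.4% in neuron-like cells with an inhibitory gene and 4.32% in those with SLC17A6. The age of the organoids, which the design names, stays open and untested, because day and library cannot be separated here.

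Fewer neuron-like cells held an inhibitory gene at day 62. Depth is argued against, since the share was lower at day 62 both after thinning to equal depth and before it (34.8% against 63.6%). Before thinning, neuron-like cells of day 62 were the deeper ones, with a median of 6645 UMIs (6520 to 6790) against 6003 (5931 to 6081). That ratio of 1.11 would raise an unthinned share. Inhibitory neurons left in unnamed clusters are argued against by the ratio over all kept cells thinned to 500 UMIs, a depth that left out 0 cells, of 0.395 (5.27% against 13.4%). In the shallow clusters these shares were 8.11% for cluster 11 of day 62 and 15.4% for cluster 2 of day 30. Among PAX2-positive neuron-like cells the share was 58.6% at day 62 and 71.1% at day 30, and PAX2-positive cells were themselves fewer (14.3% against 34.3%). The inhibitory genes differed among PAX2-positive cells, with GAD2 seen in 27.1% at day 62 against 40% at day 30, and SLC6A5 in 20.1% against 33.0%. GAD1 was seen in 12.9% against 14.9%, with overlapping intervals, and SLC32A1 in more cells at day 62, 28.5% against 21.3%. A lower share of inhibitory neurons or a lower level of GAD2 and SLC6A5 in each could contribute. So could a difference between the 2 libraries unrelated to age, and these values do not separate them.

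Clusters 1 and 13 had little mitochondrial RNA, 0.320% and 0.216% of UMIs against 1.93% and 4.18% in the other cells of their libraries, and were deeper than their library median. Clusters 3, 0 and 12 were also below the other cells of their libraries, at 0.551%, 0.856% and 0.940%. Loss of cytoplasm that leaves nuclei is argued against by ribosomal protein shares at least 1.61 times those of the other cells (28.5% against 13.4%, and 14.1% against 8.73%). A mixture of other clusters would lie between them, and at least 51 genes in each cluster lay above every other cluster of the library. Every cluster had such genes, however, from 3 in cluster 14 to 107 in cluster 11. The count could hardly have come out otherwise, so it cannot decide on doublets. Endoplasmic reticulum stress genes were higher than in the named clusters by a median log2 ratio of at least 1.57 in both clusters, in line with a stress response of these cells, with HSPA5 and HLA-B among the genes of cluster 1 that lay above every other cluster and CRYAB and GDF15 among those of cluster 13. The same ratio was 1.32 in cluster 0, 1.05 in cluster 12 and −0.32 in cluster 3, so these genes were not particular to clusters 1 and 13, and the low mitochondrial share of cluster 3 came without them. The p53 target and apoptosis genes were at 0.82 in cluster 1 and 2.18 in cluster 13, there above the 1.59 of endoplasmic reticulum stress genes. Glycolysis and hypoxia genes were at 0.90 in cluster 1 and 0.61 in cluster 13, so other stress lists were higher too. Whether the response arose in culture or during dissociation was not tested.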
